A study of Mus musculus with 6 samples.

How the data were processed

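Total RNA from 6 decidualizing uterine horns, 3 Bmp2 f/f and 3 Bmp2 d/d, was isolated with a QIAGEN RNeasy kit and 5 ug of it was made into biotin-labelled cRNA for Affymetrix arrays, per the labels' protocols. The authors deposited 1 intensity value per probe set and array on a linear scale. How probe intensities were summarised into these values, and how arrays were scaled, was not given in the sources used here. The values hold no detection calls. Groups were taken from the sample titles. Horn numbers 1 to 3 are shared by both groups and were used only to name arrays.

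Of 45101 probe sets, 64 control probe sets were left out. GEO's platform annotation gave 34945 of the rest 1 gene symbol, 932 several and 9160 none. Of the former, 34741 were matched by gene number to the gene table of the GRCm38.p6 assembly, used for names only. Probe sets with several genes were not named.

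The deposited intensity values were used without further normalization, because the array medians spanned 0.105 on the log2 scale, under the limit of 0.5 set for it. Values under 1 were set to 1, which moved 1 value, and log2 was taken with no pseudocount. The upper 60% of probe sets by mean log2 value, 27022, were tested with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend), two-sided, with Benjamini-Hochberg adjustment over all of them and a threshold of 0.05. A gene was counted once, by its brightest single-gene probe set, which gave 13686 genes. Residual degrees of freedom were 4 and the prior added 3.84. Background was gauged from 27 bacterial control probe sets, taken to have no added RNA. Their 95th percentile within each array, averaged over the 6 arrays on the log2 scale, was 6.37. A gene with a group mean below it has a fold change limited by background.

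Before the data were examined, 34 gene lists were written from textbook knowledge of the uterus, of signalling pathways and of cell types. Lists with at least 5 measured members, 31 of them, were tested with camera in limma at its preset correlation of 0.01, adjusted over the lists. Camera compares a list with all other genes. Camera with an estimated correlation and fry were run beside it. Members were also counted with p-values adjusted over the list alone.

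The genes named were chosen by a rule fixed at the same time. It takes Bmp2, the 12 largest changes in each direction among genes past the threshold whose groups did not overlap, and the up to 4 members of each list with the smallest p. It also takes 12 genes of decidualization whatever their values, and, among the 200 genes with the smallest p, the 4 most abundant in each direction. Clone-like symbols were left out of the largest changes. Genes outside the rule are said to be so where they are named.

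The steps were tested on simulated data in which 200 of 27022 probe sets were changed between 3 d/d and 3 f/f arrays. They recovered 20% of the probe sets changed 1.5-fold, 82% at 2-fold and 100% at 4-fold and 8-fold. Of 168 probe sets called, 13 were unchanged ones. The median absolute error of the log2 change was 0.0989. A list of 34 shifted genes was found, and 0 other lists were called. The simulated probe sets were independent of each other, which real ones are not. Their noise was normal, with the variances already adjusted by eBayes, and no array was set apart from its group. The shares recovered therefore need not hold for the real arrays.

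Alternatives fixed before the data were examined were quantile normalization, median centring, no filter or the upper 40%, log2 of the value plus 32, eBayes without a trend or with robust settings, array weights, a 1.5-fold minimum, a threshold of 0.01, the mean of a gene's probe sets, probe sets without the suffixes for shared sequence, the horn number as a block, and leaving out each array. A covariate for RNA integrity, the log2 ratio of the 3' to the 5' actin control probe set, was added after seeing the data. Each setting that read 1 probe set per gene chose the brightest anew. Arrays of one group did not hold identical values: their median absolute log2 difference ran from 0.119 to 0.278. Between groups it ran from 0.184 (f/f 3 and d/d 3) to 0.312 (f/f 3 and d/d 2), so the 2 ranges overlapped. Figures were drawn with matplotlib 3.10.9.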

Results

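Gene expression was measured in the decidualizing uterine horn of the mouse, the tissue in which stromal cells turn into decidua. The time point, and how decidualization was started in these horns, were not given in the sources used here. Bmp2 encodes a secreted growth factor of the bone morphogenetic protein (BMP) family. Bmp2 f/f mice carry Bmp2 alleles flanked by recombination sites. In Bmp2 d/d mice the Cre recombinase, driven from the progesterone receptor gene, removes the flanked part in the uterus. There were 3 f/f and 3 d/d arrays, each from a separately numbered horn. The labels did not say that horns of a group came from separate animals, so p-values measure only the spread between these samples. Median intensity ran from 90.3 to 97.1 over the 6 arrays, and their number limits the precision. The ratio of the 3' to the 5' actin control probe set, which increases as RNA breaks down, averaged 2.37 ± 0.48 in f/f and 2.50 ± 1.41 in d/d (SD, n = 3 each; exact two-sided permutation p = 1). Its highest value, 4.11, was that of d/d 2. Principal components, the main axes of variation between arrays, were taken over the probe sets tested. The first (44.1% of the variance) separated f/f from d/d. The second (37.8%) set f/f 1, f/f 2 and d/d 2 apart from f/f 3, d/d 1 and d/d 3. Actin ratios were 2.75, 2.52 and 4.11 in the former and 1.83, 1.93 and 1.46 in the latter. All changes below are d/d minus f/f on the log2 scale, with their standard error (SE).

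The comparison of d/d with f/f asked which genes of the decidualizing horn differ between the genotypes. No arrays came from mice with the recombinase and intact Bmp2. Effects of Bmp2 loss therefore cannot be told apart from those of the recombinase, or of driving it from the progesterone receptor gene. Bmp2 itself was 44.6-fold lower in d/d. Its log2 intensity was 10.85 ± 0.33 in f/f and 5.37 ± 0.32 in d/d (SD, n = 3 each), a change of -5.48 (SE 0.21; limma adjusted p = 0.000198). The f/f arrays read 1991, 2199 and 1426 intensity units, and the d/d arrays 36.7, 53.3 and 36.1. An exact two-sided permutation test of the 6 values gave p = 0.1, the smallest that 3 against 3 allows. A single probe set named Bmp2. Its values separated the arrays as the labels do. Which exons it reads was not given in the sources used here, so whether it reads the deleted part itself is open. The d/d level lay within the range of the bacterial control probe sets, so the fold change is limited by background.

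In d/d horns 418 genes were higher and 508 lower than in f/f, of 13686 genes tested with limma at an adjusted p under 0.05. Of these, 96 were at least 2-fold higher and 81 at least 2-fold lower. The largest falls after Bmp2 were in Prkg2, a cGMP-dependent protein kinase, which fell by 2.72 (SE 0.20), and in Tdo2, a tryptophan-degrading enzyme of decidual cells, which fell by 2.65 (SE 0.33). Further large falls were in Ptx3 (-2.50), Plekhg4 (-2.39), Kazald1 (-2.28), Sct (-2.15), Rrm2 (-2.04), Hk2 (-2.03), Serpinb9b (-2.01), Aoc1 (-2.01) and Ptgs2 (-2.01). The largest increases were in the calcium-binding protein gene Calb1 (2.61, SE 0.29), in the nucleotide-sugar receptor gene P2ry14 (1.88, SE 0.19) and in the ubiquitin ligase gene Rnf128 (1.84, SE 0.20). Dio2, which activates thyroid hormone, rose by 1.78, Padi1 by 1.78, Lcn2 by 1.76, Sprr2f by 1.72, Dbp by 1.70, Plet1 by 1.65, Car2 by 1.64, Gabrp by 1.61 and Adh1 by 1.60. For Calb1, P2ry14, Ptx3, Kazald1, Sct, Serpinb9b and Ptgs2 the lower group lay within the range of the bacterial controls, as it did for 52 genes past the threshold, and their fold changes are limited by background. With the mean of a gene's probe sets Gabrp rose by 1.07, Dio2 by 1.12 and Plet1 by 1.09. The other probe set of Gabrp gave 0.53. It was the brighter one, and so the one read, without d/d 1 (0.44, past no threshold) and without d/d 2 (0.64). On the probe set first given, the d/d arrays read 8.07 to 8.58 in log2 intensity and the f/f arrays 6.44 to 7.12.

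Among the most abundant genes with small p, Ran, a nuclear transport GTPase, fell by 0.43 (SE 0.07), Ldha, lactate dehydrogenase A, by 0.49 (SE 0.08), C1qbp by 0.54 (SE 0.08) and the chaperone gene Hsp90aa1 by 0.58 (SE 0.09). Timp2, an inhibitor of matrix proteases, rose by 0.65 (SE 0.10), as did the membrane protein gene Tmem176b. Pcp4 rose by 0.71 (SE 0.10) and the matrix protein gene Dpt by 0.64 (SE 0.09). By probe set, 563 were higher and 818 lower, of 27022 tested. All 926 genes past the threshold had 3 d/d values on one side of all 3 f/f values. Such separation was seen in 33.5% of all genes tested, against 10% by chance. Ran lost its call with eBayes without a trend and was at -0.71 without probe sets of shared sequence, where C1qbp lost its call, and Hsp90aa1 and Timp2 lost theirs with the mean of a gene's probe sets.

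The number of these single-gene calls depended on which array was left out. Without f/f 1, Bmp2 alone passed. Without f/f 2, Bmp2 and the ribonucleotide reductase gene Rrm2 passed. Without d/d 1, 1 gene was higher, Adh1, and 3 were lower, Bmp2, Rrm2 and Gjb2, a connexin gene named here only after its values were seen. Without d/d 3, 80 genes were higher and 102 lower. Without f/f 3 the counts were 385 and 437, and without d/d 2 they were 479 and 663. At an unadjusted p under 0.05, 3536 genes differed over all arrays, 2737 without f/f 1, 2401 without f/f 2 and 2706 without d/d 1. The limit applies to every single gene named below. Without f/f 3, Alpl (-0.75), Wnt6 (-0.57), Notum (-0.87), S100a8 (-1.30), Cxcl12 (0.89), Ltf (2.30) and Lyz2 (adjusted p = 0.0412) also passed, and without d/d 2 so did Gdf10 (-0.86), S100a8 (-1.20), Hoxd9 (0.56) and Tie1 (0.64).

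**Figure D1:**
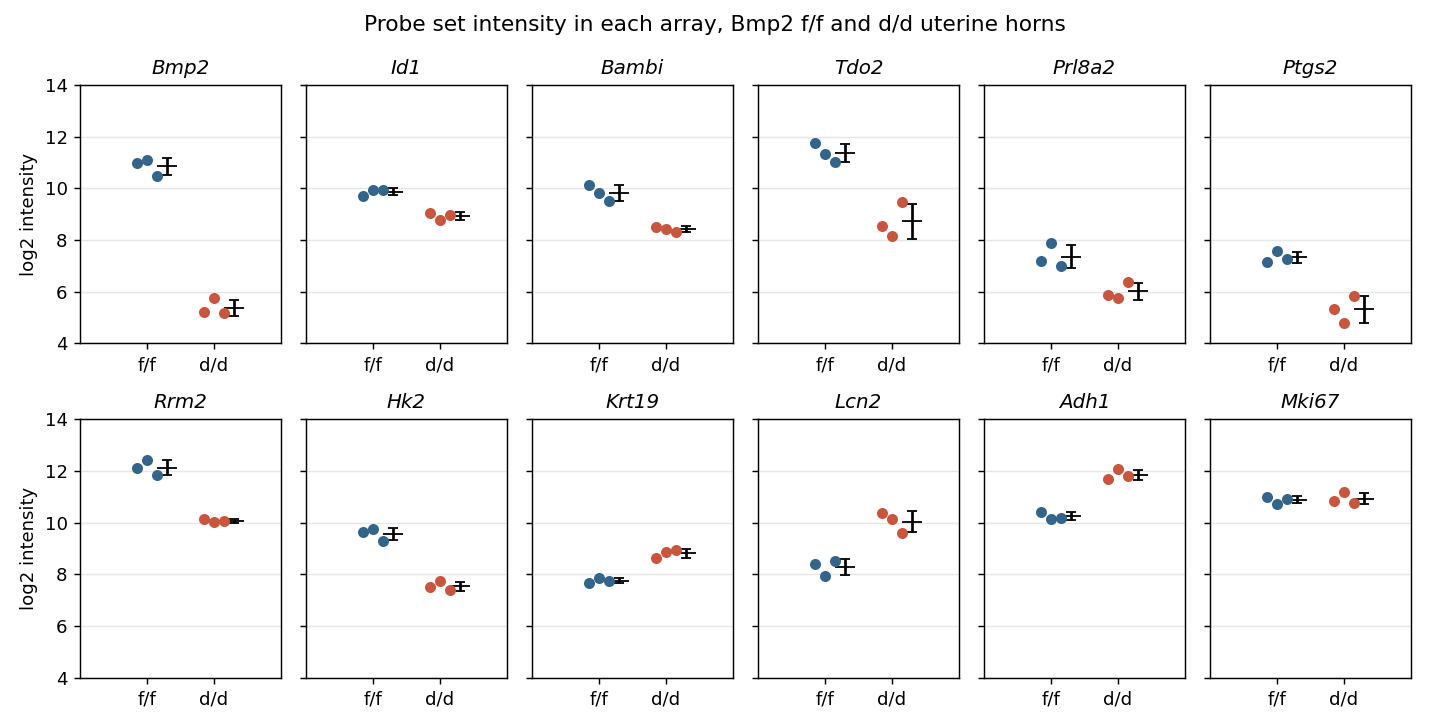
Log2 intensity of 12 genes in each array, f/f in blue and d/d in red, with group mean and SD (n = 3) as black bars. Bmp2, Id1, Bambi, Tdo2, Prl8a2, Ptgs2, Rrm2 and Hk2 were lower in d/d, Krt19, Lcn2 and Adh1 were higher, and the groups overlapped for Mki67, with a change of 0.04.

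Id1 and Id3, inhibitor of differentiation genes that BMP signalling induces in many tissues, were lower in d/d. Id1 fell by 0.93 (SE 0.13; adjusted p = 0.0164) and Id3 by 0.93 (SE 0.14). Id2 and Id4, named after their values were seen, differed by 0.39 (adjusted p = 0.154) and 0.71 (adjusted p = 0.215). Bambi, a membrane decoy receptor, fell by 1.40 (SE 0.17; adjusted p = 0.0158). Of 19 measured BMP target genes and antagonists, 6 fell and 3 rose, against 7 and 4 when adjusted over the list alone. Smad7 fell by 1.19, Fst by 1.04 and Bmper by 0.92, and Dlx5 rose by 0.62; these 4 were named after their values were seen. Tgfb1i1 rose by 0.67 (SE 0.11). Msx1 rose by 0.76 with its brighter probe set, whereas its other probe set gave -0.14. The list had a median change of 0.24 and a mean of -0.11, and camera, which leaned lower, did not call it (adjusted p = 0.549). Of 19 measured BMP ligands, receptors and SMADs, only Bmp2 passed over all genes, and 3 were higher and 2 lower when adjusted over the list alone. Smad1 differed by 0.58 (adjusted p = 0.0626) and Gdf10 by -0.66 (adjusted p = 0.0983). The median was 0.07, with 13 of 19 members positive. The mean was -0.23, but it includes the deleted gene Bmp2 itself, at -5.48, so its sign says little of the other members. Camera, run with Bmp2 in the list, gave adjusted p = 0.996.

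Markers of decidual stroma were lower in d/d. Of 22 measured, 8 fell and 2 rose, against 9 and 2 when adjusted over the list alone, with a median change of -0.44. Tdo2 and Aoc1 led the falls. Prl8a2, a decidual prolactin family gene, fell by 1.35 (SE 0.26), with its d/d level in the range of the bacterial controls. Gja1, the gap junction protein connexin 43, fell by 0.63 (SE 0.10), and the transcription factor gene Hand2 by 0.78 (SE 0.17). The list also holds Fst and Ptn, which fell by 0.52, and the protease genes Htra1 and Htra3, which rose by 0.94 and 1.20. Htra1 and Ptn were named after their values were seen. Alpl differed by -0.50 (adjusted p = 0.253) and Hoxa10 by 0.14 (adjusted p = 0.753). Prl3c1 was too dim for the test set; with no filter it was lower (adjusted p = 0.0229), from a log2 level of 6.47 in f/f to 4.61 in d/d. The d/d level lay in the range of the bacterial controls, so the size of its change is limited by background. Camera called the list lower (adjusted p = 0.00405; adjusted p = 0.302 with an estimated correlation). Without d/d 2 its call was lost (adjusted p = 0.0904), with a median of -0.41. Over the alternatives its adjusted p ranged from 0.000532 to 0.302. The f/f arrays were uneven: the list's mean, relative to that of the 6 arrays, was 0.29, 0.28 and 0.05 in f/f 1 to 3. In d/d 1 to 3 it was -0.20, -0.26 and -0.15. Epithelial markers were higher in the same arrays, by a median of 0.84.

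The Wnt, progesterone receptor and prostaglandin lists are topics that the series description itself names from these arrays, so they are not independent evidence of direction. Of 27 measured Wnt ligands and receptors, 3 rose and 2 fell, with the same counts when adjusted over the list alone. Wnt4, a ligand needed for decidualization, fell by 1.15 (SE 0.25; adjusted p = 0.0422), and the receptor gene Ror1 by 0.98 (SE 0.17). The receptor genes Fzd6 and Fzd7 rose by 0.68 and 0.72, and Rspo3, an enhancer of Wnt signalling, by 1.20 (SE 0.25). Wnt6 differed by -0.36 (adjusted p = 0.310) with its brighter probe set, whereas its other probe set gave -0.94 and passed (adjusted p = 0.0479). The other probe set of Wnt4 gave -0.46. Without f/f 2 it was the brighter one, and Wnt4, read by it, was at -0.34 and no longer passed. Of 21 Wnt inhibitors and canonical targets, Sfrp4, a secreted Wnt antagonist, rose by 1.16 (SE 0.14) and Axin2, a canonical target, by 0.64 (SE 0.11). Adjusted over the list alone, 4 were higher and 2 lower. Nkd2 differed by 0.92 (adjusted p = 0.0640) and Notum by -0.68 (adjusted p = 0.0749). Camera called neither list, with adjusted p = 0.792 for both and medians of 0.05 and 0.06. With the mean of a gene's probe sets, Fzd6, Axin2, Hand2 and Msx1 no longer passed, nor did Fzd7 with median centring or Hand2 with eBayes without a trend.

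Pgr, the progesterone receptor, differed by -0.12 (SE 0.10; adjusted p = 0.569). Of 22 measured genes of progesterone receptor signalling, 3 fell and none rose. Ihh, an epithelial ligand, fell by 1.40 (SE 0.22), with a d/d level in the bacterial control range, and the co-chaperone gene Fkbp5 by 0.75 (SE 0.14). The third was Hand2. Zbtb16 differed by 0.60 (adjusted p = 0.0508). Adjusted over the list alone, 4 were higher and 5 lower. The median was 0.01, the mean -0.04, and camera gave adjusted p = 0.741. Of 21 prostaglandin genes, Ptgs2, the inducible cyclooxygenase, fell by 2.01 (SE 0.26; adjusted p = 0.0160), and Hpgd, which inactivates prostaglandins, rose by 1.15 (SE 0.23). Adjusted over the list alone, 3 were higher and 2 lower. Rxra differed by -0.47 (adjusted p = 0.0641) and Ptgis by 0.71 (adjusted p = 0.0868). The list had a median of 0.02 (camera adjusted p = 0.996).

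Cell cycle genes were lower in d/d. Of 34 measured, 10 fell and none rose over all genes, and 16 fell when adjusted over the list alone, with a median of -0.32. Rrm2, which makes deoxynucleotides, fell by 2.04 (SE 0.15; adjusted p = 0.00766). Cdc6, which loads the replicative helicase, fell by 1.25 (SE 0.15), and the helicase genes Mcm4 and Mcm5 by 0.82 (SE 0.11) and 0.70 (SE 0.09). Mki67, a marker of dividing cells, differed by 0.04 (SE 0.13; adjusted p = 0.915). Mcm5 lost its call without probe sets of shared sequence. Epithelial and decidual stroma markers also moved in these arrays, with medians of 0.84 and -0.44. Whether the shares of these cell types set the cell cycle shift was not tested. Camera called the list lower (adjusted p = 2.11e-08; adjusted p = 0.302 with an estimated correlation), and its adjusted p ranged from 6.50e-10 to 0.302 over the alternatives. Of 16 endoreplication and cyclin D regulators, 3 fell, over all genes and over the list alone, and 1 was higher when adjusted over the list alone. E2f8 fell by 1.17 (SE 0.21), E2f7 by 0.68 (SE 0.11) and Gmnn, an inhibitor of replication licensing, by 0.56 (SE 0.11). Cdkn2c differed by 0.38 (adjusted p = 0.0902). The median was -0.08 and camera did not call the list (adjusted p = 0.289).

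Glycolysis and hypoxia genes were lower, with 5 falling and 1 rising of 21 measured, and 8 and 1 when adjusted over the list alone. Hk2, which phosphorylates glucose, fell by 2.03 (SE 0.16; adjusted p = 0.00766). The collagen hydroxylase gene P4ha2 fell by 0.97 (SE 0.12), Ldha by 0.49 and the phosphoglycerate mutase gene Pgam1 by 0.41 (SE 0.08). The member that rose was Hk1, by 0.61, named after its values were seen. The median was -0.18 (camera adjusted p = 0.00178; adjusted p = 0.302 with an estimated correlation), in a range of 0.000532 to 0.302 over the alternatives. In the same arrays epithelial markers were higher, by a median of 0.84, and decidual stroma markers lower, with a median of -0.44. Of 23 angiogenic factors, Apln fell by 1.17 (SE 0.13), Vegfa, vascular endothelial growth factor A, by 1.02 (SE 0.18) and Angpt1 by 0.73 (SE 0.17), and none rose. Adjusted over the list alone, 2 were higher and 3 lower. Cxcl12 differed by 0.72 (adjusted p = 0.0529). The median was 0.04 although camera leaned lower (adjusted p = 0.996). Angpt1 had adjusted p = 0.0498 and lost its call with quantile normalization, with median centring and with no filter, and Pgam1 with eBayes without a trend. Vegfa fell by 0.60 with the mean of its probe sets.

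Epithelial markers were higher in d/d. Of 23 measured, 11 rose and none fell, against 15 and 1 when adjusted over the list alone, with a median of 0.84. The keratin genes Krt19 and Krt18 rose by 1.07 (SE 0.13) and 1.05 (SE 0.18), the adhesion molecule gene Epcam by 1.01 (SE 0.15) and Rab25, an epithelial trafficking GTPase, by 0.84 (SE 0.11). Prss28 and Prss29, uterine gland proteases named after their values were seen, differed by -0.87 and -0.37. Camera called the list higher (adjusted p = 4.60e-06; adjusted p = 0.302 with an estimated correlation), in a range of 1.02e-07 to 0.302 over the alternatives. Of 15 oestrogen receptor and target genes, 3 rose and none fell, and 11 were higher and 1 lower when adjusted over the list alone. They were Padi1, Lcn2 and the mucin gene Muc1, which rose by 1.07 (SE 0.23). Ltf, lactoferrin, differed by 1.80 (SE 0.47; adjusted p = 0.0717) and Mad2l1 by -0.43 (adjusted p = 0.0561). Muc1 and Ltf are also on the epithelial list. The median was 0.45 (camera adjusted p = 0.000191; adjusted p = 0.302 with an estimated correlation), in a range of 5.69e-06 to 0.302. Muc1 lost its call with quantile normalization.

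Matrix proteases and their inhibitors were higher, with 5 rising and 1 falling of 20 measured, and 8 and 1 when adjusted over the list alone. Mmp11, a stromal metalloproteinase, rose by 1.19 (SE 0.11; adjusted p = 0.0134), and Plat, tissue plasminogen activator, by 0.65 (SE 0.10). Adamts9 fell by 0.96 (SE 0.12). Epithelial, endothelial and decidual stroma markers had medians of 0.84, 0.27 and -0.44 in the same arrays. Whether shares of cell types set the protease shift was not tested. The median was 0.34 (camera adjusted p = 0.00178; adjusted p = 0.302 with an estimated correlation), in a range of 0.000845 to 0.302. Of 34 extracellular matrix genes, 5 rose and 1 fell, and 7 were higher and 3 lower when adjusted over the list alone. Lama2 rose by 0.80 (SE 0.16), Col18a1 by 0.67 (SE 0.12), Col6a1 by 0.57 (SE 0.11) and Col5a1 by 0.53 (SE 0.10). The median was 0.17, and camera just missed its threshold (adjusted p = 0.0544). That list passed in 8 alternatives, among them quantile normalization (adjusted p = 0.0158), without f/f 3 (0.00336) and without d/d 2 (0.000250), in a range of 0.000112 (array weights, a fit that rests on 1 array) to 0.836. Col5a1 lost its call with the mean of a gene's probe sets, and Col6a1 with median centring.

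Interferon response genes were higher as a list. Of 21 measured, 2 rose, Psmb8 of the immunoproteasome by 0.63 (SE 0.12) and the GTPase gene Gbp3 by 0.64 (SE 0.15), and none fell. Adjusted over the list alone, 11 were higher. Usp18 differed by 0.70 (adjusted p = 0.0579) and Gbp2 by 0.64 (adjusted p = 0.0643). The median was 0.43 (camera adjusted p = 3.26e-05; adjusted p = 0.337 with an estimated correlation), in a range of 1.61e-06 to 0.337. The shift was uneven over the d/d arrays: the list's mean, relative to that of the 6 arrays, was 0.05, 0.36 and 0.19 in d/d 1 to 3, in the same order as the macrophage and dendritic cell list, at -0.11, 0.52 and 0.19. The interferon median ran from 0.25 (array weights) to 0.59 (without d/d 1) over the alternatives. Gbp3 lost its call with median centring and with no filter. Of 19 endothelial markers, Tek, an angiopoietin receptor, rose by 0.66 (SE 0.12), and 5 were higher when adjusted over the list alone. Tie1 differed by 0.53 (adjusted p = 0.0745), Vwf by 0.90 (0.0804) and Mmrn2 by 0.53 (0.0903). The other 3 probe sets of Mmrn2 gave 0.47 to 0.57, and at least 1 of them passed (lowest adjusted p = 0.0423). The endothelial median was 0.27 (camera adjusted p = 0.00265; adjusted p = 0.337 with an estimated correlation), in a range of 0.000833 to 0.337.

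Of 19 macrophage and dendritic cell markers none passed over all genes, and 2 were higher when adjusted over the list alone. Cd14 differed by 0.97 (adjusted p = 0.0559), Lyz2 by 0.81 (0.0662), Tyrobp by 0.62 (0.102) and C1qa by 0.66 (0.120). Camera called the list higher (median 0.35; adjusted p = 0.00265; adjusted p = 0.836 with an estimated correlation). Without d/d 2, whose mean over the list lay 0.52 above that of the 6 arrays, the call was lost (median 0.17; adjusted p = 0.0748), in a range of 3.22e-06 to 0.836 over the alternatives. Of 19 Hox and homeobox genes, 3 rose, Msx1, Hoxb6 by 0.69 (SE 0.15) and Meis2 by 0.56 (SE 0.12), and 5 were higher when adjusted over the list alone. Hoxd9 differed by 0.46 (adjusted p = 0.0888). Camera called this list higher (median 0.15; adjusted p = 0.0379; adjusted p = 0.302 with an estimated correlation). Its call was lost without f/f 1 (0.0656), f/f 2 (0.0600), d/d 1 (0.0584), d/d 2 (0.0572) or d/d 3 (0.211), in a range of 0.0180 to 0.302. The medians in those settings were 0.16, 0.12, 0.16, 0.15 and 0.21, in that order. Hoxb6 lost its call with median centring and with no filter, and Meis2 with no filter and with the mean of a gene's probe sets.

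Of 20 EGF and FGF signalling genes, Hbegf, a heparin-binding growth factor of the EGF family, was 2.01-fold lower and Fgf7 fell by 0.58 (SE 0.12), over all genes and when adjusted over the list alone. Erbb3 differed by 0.63 (adjusted p = 0.119). The median was 0.04, the mean -0.02, and camera gave adjusted p = 0.670. Of 10 steroid synthesis genes, Cyp11a1, the side-chain cleavage enzyme, fell by 1.45 (SE 0.29), with a d/d level in the bacterial control range, and Hsd17b11 rose by 1.06 (SE 0.14). Adjusted over the list alone, 2 were higher and 3 lower (median -0.12; camera adjusted p = 0.670). Of 16 retinoid genes, Aldh1a2, which makes retinoic acid, rose by 0.50 (SE 0.11), over all genes and when adjusted over the list alone (median -0.13; camera adjusted p = 0.784). Of 21 inflammatory genes, Ptx3 fell and Lcn2 rose, in both adjustments (median 0.06; camera adjusted p = 0.947). None of 17 Notch genes passed over all genes, and 3 were higher when adjusted over the list alone (median 0.09; camera adjusted p = 0.531). Aldh1a2 lost its call with median centring and with no filter, and Fgf7 with no filter.

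The remaining cell type lists were not called over all arrays. Of 18 smooth muscle markers, Pcp4 and Synpo2 rose, in both adjustments, and Synpo2 did so by 0.52 with 1 probe set while its other 3 probe sets were negative, and not with median centring (list median 0.15; camera adjusted p = 0.0949). Of 13 stromal fibroblast markers Dpt rose, and adjusted over the list alone 2 were higher and 1 lower (median 0.12; adjusted p = 0.174). Camera called both lists higher without d/d 2, with adjusted p = 0.00627 and 0.0137, and the smooth muscle list also without f/f 3 (0.00336), in ranges of 0.00335 (array weights) to 0.836 and 0.0137 to 0.512. None of 12 natural killer cell markers passed in either adjustment (median 0.28; adjusted p = 0.133), but camera called that list without f/f 2 (0.0170), in a range of 0.0170 to 0.836. None of 7 adipocyte markers passed in either adjustment (median 0.44; adjusted p = 0.597), and camera called that list without d/d 3 (0.00502), in a range of 0.00502 to 0.910. The neutrophil list had 8 members and none past the threshold over all genes, 1 higher over the list alone, a median of 0.04 and a camera test that leaned lower (adjusted p = 0.996). Its member S100a8 differed by -0.97 (adjusted p = 0.112). For 5 T and B lymphocyte markers and 5 mast cell markers the medians were 0.09 and 0.03 (adjusted p = 0.865 and 0.690), with none past the threshold over all genes and, adjusted over the list alone, 1 mast cell marker higher. Erythrocyte, mesothelium and trophoblast lists had 4 measured members each and no list test, with medians of 0.02, 0.40 and 0.06. Krt19 was their only member past the threshold over all genes, and adjusted over the list alone 2 mesothelium markers were higher.

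Of 31 lists tested, camera with its preset correlation called 7 higher and 3 lower. With an estimated correlation 0 passed, and 3 had an unadjusted p under 0.05. By fry, which tests whether the genes of a list move on balance one way, 9 lists passed, 6 higher and 3 lower. The list of macrophage and dendritic cell markers was the one it did not call (adjusted p = 0.246).

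**Figure D2:**
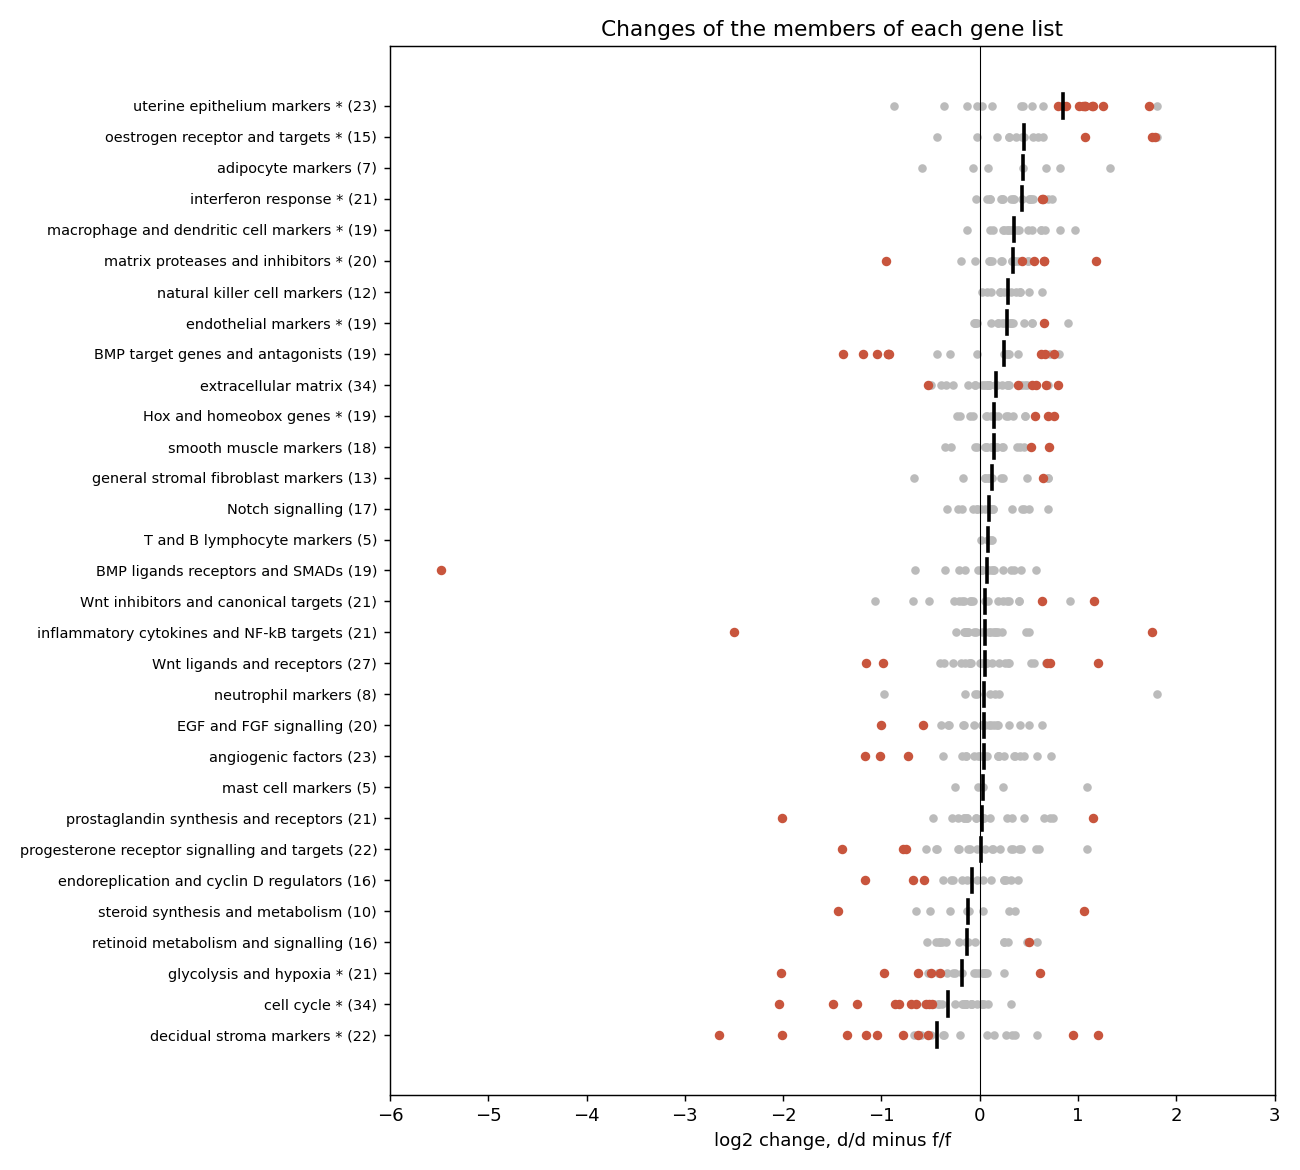
Log2 change (d/d minus f/f) of every measured member of the 31 lists tested, in red where the gene passed an adjusted p under 0.05 and in grey otherwise, with the median as a black bar. Measured members are in brackets and a star marks lists called by camera with its preset correlation. The epithelial list has the highest median, 0.84, and the decidual stroma list the lowest, -0.44.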

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

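Tests of a lower stroma share, of a uniform epithelial gain, of a lower share of dividing cells, of RNA integrity from the order of the arrays, and of the actin ratio as a covariate, in its real and its other orders, were chosen only after the results were seen. An 18S ribosomal RNA control probe set near the 3' end, outside the comparisons, read 1736 intensity units on d/d 2, which was 3.15 times the highest f/f array, 551. It read 551 and 462 on f/f 1 and f/f 2, against 159, 152 and 123 on f/f 3, d/d 1 and d/d 3. The middle 18S probe set read 615 on d/d 2, 2.07 times the highest f/f array, 297. Each was picked out for exceeding the f/f arrays by over 2 times at over 100 units.

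Epithelial markers were higher in d/d, with a median change of 0.84. If stroma alone had a lower share, epithelium and smooth muscle should move alike, provided that stroma does not express the smooth muscle markers. The epithelial shift exceeded the smooth muscle shift by 0.504 (SE 0.179, exact two-sided permutation p = 0.1, the smallest possible). Smooth muscle means overlapped between groups, with f/f 3 at 0.11 and d/d 2 at -0.01. Whether stroma expresses these markers was not tested, so the difference does not decide on a lower stroma share. A uniform gain of epithelial cells should move their markers alike, provided that no marker is itself regulated. Of 14 well-measured markers, 4 lay over 2 SE below the median shift of 1.03: Spint1, Cdh1, Prss28 and Prss29. Prss28 and Prss29 were negative, at -0.87 and -0.37. This rule was written after the results were seen, and regulation of single markers was not tested, so it does not decide on a uniform gain. The actin ratio of d/d 2 lay above and that of d/d 3 below every f/f array, yet both had an epithelial mean above every f/f array, by 0.371 or more against an f/f SD of 0.132, which argues against the ratio alone setting the shift. A lower share of stroma and a uniform gain of epithelial cells thus stay open. A gain in part of the epithelium, or regulation within it by the Bmp2 genotype, may also underlie the shift, and neither was tested.

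DNA replication genes were lower in d/d while genes of G2 and mitosis moved less: 8 of 14 fell with a median of -0.60, against 2 of 20 with a median of -0.15. A lower share of dividing cells should lower both parts alike where those cells pass through both. The replication shift lay below the mitosis shift by a change of -0.528 (SE 0.119, exact two-sided permutation p = 0.1, the smallest possible). This comparison was chosen after the results were seen, so it is no independent evidence. It cannot exclude fewer endoreplicating cells, which copy DNA without mitosis. In d/d 2 and d/d 3 alike, the replication mean lay below every f/f array, the smaller gap being -0.558 against an f/f SD of 0.128, which argues against the actin ratio alone setting the shift. Fewer endoreplicating cells, a shift between cycle phases, or regulation of replication genes by the Bmp2 genotype, may underlie it, and none of these was tested.

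Nearly all single-gene calls were lost without f/f 1 (1 gene past the threshold), f/f 2 (2 genes) or d/d 1 (4 genes), against 926 over all arrays and 1142 without d/d 2. For the loss without d/d 1, differences in array scaling are argued against, since 2 genes passed there after quantile normalization. The losses without f/f 1 and f/f 2 were not tested in this way. With the actin ratio as a covariate 3146 genes passed, and of the 36 orders of the ratios within groups the real one was the 1 that gave as many. The highest other gave 2930, with the ratios of f/f 1 and f/f 2 (2.75 and 2.52) exchanged, the median of the others was 535, and 14 orders gave over 926. A spread within groups along the ratio may thus take part, but no other measured property was fitted, and differences between horns that follow the ratio, such as dissection or stage, were not tested.

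The 6 arrays can be split in 10 ways, too few for a share under 0.05. The real split was the 1 of 10 that gave as many genes, 926 against 0 in the highest other, and the 1 of 10 that gave as many probe sets, 1381 against 0. For lists called by camera with its preset correlation it was again 1 of 10, but with 10 lists against 7 in the highest other.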

How the results depend on the processing

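The actin covariate, and the alternatives for the lists of ribosome assembly, chaperones and the clock, were chosen after seeing the data; the other alternatives were fixed before. Bmp2 passed in all of them, with changes from -5.74 (array weights) to -4.67 (log2 of the value plus 32). Against 418 genes higher, 508 lower and 1381 probe sets, array weights gave 3300, 2918 and 11278, but with a weight of 124 for d/d 1 against 0.130 to 1.32 for the others, so that fit rests on 1 array, and the estimation of the weights stopped before it converged. The covariate gave 1673, 1473 and 5293. A threshold of 0.01 gave 1 (Adh1), 4 (Bmp2, Prkg2, Rrm2 and Hk2) and 6. The mean of a gene's probe sets gave 711 genes higher; the cause was not tested. Leaving out 1 array gave 0 to 479 genes higher, 1 to 663 lower and 1 to 1825 probe sets, the lowest without f/f 1 (for genes higher also without f/f 2) and the highest without d/d 2, and fewer arrays widen the test by construction. With an estimated correlation 0 lists were higher and 0 lower. That setting estimates how far genes of a list move together. For the Hox list the estimate, 0.0109, was near the preset 0.01, yet camera no longer called it (adjusted p = 0.302). Genes moving together were thus not shown to be why the calls were lost. Median centring gave 35.4% of calls higher against 45.1%. Msx1 changed sign without probe sets of shared sequence (-0.14), without d/d 2 (-0.21) and without d/d 3 (-0.06), read by its other probe set (leave-out range -0.21 to 0.89), and Synpo2 with the mean of its probe sets (-0.29), whose others were negative. The groups of all 926 genes did not overlap, so leaving out an array can turn a direction only where another probe set is read. Directions turned for 1 of 926 with the mean of probe sets, 5 of 906 without probe sets of shared sequence, 1 of 923 without f/f 3, 1 of 920 without d/d 2 and 1 of 921 without d/d 3.

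With the horn number as a replicate block, 351 genes were higher, 360 lower and 1145 probe sets passed, with 9 lists higher and 3 lower, the added ones being extracellular matrix and natural killer cell markers. Same-numbered arrays deviated together with correlations of -0.299, 0.229 and 0.540 across probe sets, so the numbers were not taken to pair them. Signal near background limits 52 called genes.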

Other observations

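Genes for ribosome assembly were lower in d/d. All 3 lists in this part were written after the leading genes had been seen and leave out Urb1, Rrp1b, Dbp and Hsph1, which prompted them. Their alternatives were chosen later still. The tests use the arrays that prompted the lists, so they are no independent evidence. Their p-values are adjusted over 3 lists only and cannot be set beside those of the 31 fixed lists. The genes named from them were chosen after their values were seen. Of 40 ribosome biogenesis genes, 26 fell, none rose and 39 were negative, with a median change of -0.61. Rrp12, a factor of ribosome export, fell by 1.23 (SE 0.18), Nolc1 by 1.08 (SE 0.17), Heatr1 by 0.99 (SE 0.12) and Nop56, a core protein of box C/D particles, by 0.81 (SE 0.11). The hypothesis that these genes were lower as a list passed camera (adjusted p = 1.46e-25 over the 3 lists; adjusted p = 0.0208 with an estimated correlation). It passed in all 20 alternatives, including each array left out and each scaling, with adjusted p from 3.87e-30 to 0.0208 and a median from -0.69 to -0.58. In the same arrays epithelial markers were higher by a median of 0.84, while decidual stroma markers and DNA replication genes were lower, with medians of -0.44 and -0.60, and whether shares of cell types set the shift was not tested.

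Chaperone genes were lower too. Of 26 measured, 12 fell, none rose and 25 were negative, with a median of -0.48. The mitochondrial chaperonin genes Hspd1 and Hspe1 fell by 0.79 (SE 0.10) and 0.48 (SE 0.07), the endoplasmic reticulum chaperone gene Hspa5 by 0.62 (SE 0.13), and Cct6a of the cytosolic chaperonin by 0.67 (SE 0.13). The hypothesis passed camera (adjusted p = 7.95e-15; adjusted p = 0.0156 with an estimated correlation). Without Hsp90aa1, named above among the abundant genes, the list gave adjusted p = 4.83e-14, and adjusted p = 0.0119 with an estimated correlation. The whole list passed in all 20 alternatives, with adjusted p from 3.52e-17 to 0.0156 and a median from -0.52 to -0.37. The epithelial and decidual stroma medians given above, 0.84 and -0.44, apply to the same arrays, and whether shares of cell types set the chaperone shift was not tested either.

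The clock output gene Dbp was among the largest increases, and the hypothesis that clock genes were higher as a list did not pass (adjusted p = 0.105; adjusted p = 0.155 with an estimated correlation), nor did it in any of 20 alternatives (0.0632 to 0.194). Of 17 measured, Nr1d2 rose by 0.84 (SE 0.13) and Tef by 0.75 (SE 0.12), none fell, and the median was 0.16, or 0.32 without f/f 2. Members moved both ways, with 6 of 17 negative: Per3 differed by 0.62 (limma adjusted p = 0.0786), Cry1 by -0.41 (0.0816) and Arntl by -0.34 (0.144). Camera looks for a move in 1 direction, so it cannot tell an unmoved clock from one whose members move oppositely. A shift in clock phase was not tested.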
